A study of Mus musculus with 6 samples.

How the data were processed

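The data are polyA RNA-seq libraries from in vitro differentiated mouse Tregs, 3 treated with DEL-1-Fc and 3 with the Fc control, which are the only groups of the series. RNA was extracted with Trizol and treated to remove DNA, and BGI made the libraries, per the labels' protocols. The deposited files hold raw counts of reads per gene, 1 file per library, and per the submitters' processing notes the tools were STAR (no version given) and HTSeq 0.6.0 with the GRCm38 (mm10) build. The annotation release, the strand setting and how multi-mapping reads were treated are not given in the sources used here. Genes that overlap others, or share sequence with copies, are therefore reported as uncertain. Each file lists 39179 gene identifiers with no summary rows. Of these, 37693 matched GENCODE M21 (GRCm38), which gave symbols, biotypes, coordinates, exon lengths and GC content. The 37 genes of the mitochondrial genome had 0 counts in every library, so the list of mitochondrially encoded mRNAs was not tested.

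Groups were taken from the treatment labels. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total count 15) kept 14928 genes, TMM scaled the libraries, and the quasi-likelihood test with robust dispersion compared DEL-1-Fc with Fc, with Benjamini-Hochberg adjustment over all genes kept and calls at 0.05. The common biological coefficient of variation was 14.4%. CPM values use TMM-scaled library sizes. Log2 fold changes are DEL-1-Fc over Fc, and their SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. No fold threshold was applied.

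Before the data were examined, 32 gene lists and 13 lists of cell type markers were fixed. Of their 905 symbols, 5 were not matched and 1 was matched through a synonym. Lists with at least 5 genes kept were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 31 lists, and again with an estimated correlation and with fry. Counts adjusted over the list alone use the edgeR p-values of that list's genes only. The rule for named genes was also fixed: 18 genes always named; the 10 largest rises and 10 largest falls among called genes with separated groups and a mean of at least 5 CPM, leaving out predicted genes and pseudogenes; and up to 4 members with the smallest p of each list in the text. Some genes the rule names are not reported here. Genes named outside this rule were chosen after their values were seen, including all marker genes named singly.

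The library totals of 33364166 to 61967687 counts differ by up to 1.86-fold. A gene with 0 counts could still be present at up to 3 counts, which is 0.0484 CPM in the deepest and 0.0899 CPM in the shallowest library. That bound covers counting error only. Replicates of a group differed far more than counting noise, with a chi-square per degree of freedom of at least 18.4 for every pair, so no file holds a copy of another's counts. Repeat libraries of one culture are not excluded by this.

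The scripts were tested on counts simulated from the means, library sizes and dispersions of these libraries, with 200 genes changed between simulated DEL-1-Fc and Fc. Among 14928 genes, edgeR called in the right direction 43.3% of the genes changed by a log2 of 0.5, 68.7% of those changed by 1 and 93.9% of those changed by 2. In this draw 9.87% of the edgeR calls were unchanged genes, against 18.9% of the DESeq2 calls. Over 10 further draws a mean of 7.65% of its calls were unchanged genes, above the nominal 5%. With no gene changed, a first draw called 7 genes, and over 10 further draws the median was 1 and the highest 4. Camera called all 10 shifted lists and 0 of 20 unshifted lists, with either correlation. Fry called the 10 shifted and 0 of the 20 unshifted lists. Simulated genes were drawn independently, so these list results cannot tell how often lists of correlated genes are called falsely. Estimated correlations of the real lists ranged from -0.0444 (Th17) to 0.688 (oxidative phosphorylation).

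Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE, upper-quartile or no scaling factors, no filter or a filter of 5 CPM in 3 libraries, no robust dispersion, the replicate number as a block, each library left out in turn, and an absolute log2 fold of at least 1. A prior count of 5 was also tried for the list test. Chosen after seeing the data were removal of each library's length and GC trend, thinning to the smallest library, and leaving out pseudogenes and genes that share sequence. For the last, the share of a gene's 31-base words that also occur in another gene was computed from the longest GENCODE M21 transcript of each gene, and genes at 20% or more were left out. Among the genes named in the text, Csf2, Xcl1, Maf, Eomes, Usp18, Cdkn1a, Bhlhe40, Oasl1, Il12rb2, Ctsw, Rasgrp2, Icam1, Nfkb2, Dusp5, Gfi1, Bcl6, Furin, Cd160, Pfkp, Gbp2, Itgav, Slc2a1, Runx2, Ikzf2, Elovl6, Ndrg1, Syvn1, Hspa1a, Atp5j, Cox6c, Eif2ak2 and Rnf213 overlap a gene on the other strand, and H19, Scd2, Satb1, Tapbp, Foxp1, Gbp7 and Rpl5 overlap one on the same strand. Dusp5, Cox5b, Ly6a and Il12rb2 share 21.2%, 32.6%, 22.1% and 25.7% of their 31-base words with other genes. The values of all these genes are uncertain to that extent. Figures were drawn with matplotlib from the same tables.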

Results

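Gene expression was measured by polyA-selected RNA sequencing in mouse T cells that had been driven toward the regulatory T cell (Treg) fate in culture. Naive CD4+ T cells came from spleens of wild-type C57BL/6 mice aged 6 weeks. They were cultured for 3 days with coated anti-CD3 at 2 µg/ml (the unit's first letter is garbled in the labels), anti-CD28 at 1 µg/ml, TGF-β1 at 5 ng/ml and IL-2 at 40 ng/ml. One arm received DEL-1-Fc, the secreted integrin-binding protein DEL-1 (gene Edil3) fused to an antibody Fc part, and the other received Fc alone as control. Each group had 3 libraries. The Fc libraries held 57391981, 61967687 and 55318383 counts and the DEL-1-Fc libraries 33364166, 55236703 and 58075983, so DEL-1-Fc replicate 1 was the shallowest. The labels do not say whether replicates came from separate animals or cultures, and p-values therefore measure only the spread between these libraries, which may be technical. The first principal component of log CPM (counts scaled to library size) carried 44% of the variance and separated the groups. The second carried 23.3% and set DEL-1-Fc replicate 1 apart from DEL-1-Fc replicates 2 and 3.

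The series title names DEL-1, β3 integrin, Runx-1 and Foxp3, and the design compares Tregs made with DEL-1-Fc against Tregs made with Fc. Foxp3, the transcription factor that defines Tregs, was 1.46-fold higher in DEL-1-Fc, at 523.3 ± 59.7 CPM against 359.5 ± 50.1 CPM in Fc (SD, n = 3 each; log2 fold change 0.54, SE 0.116, edgeR adjusted p = 0.0166). Runx1, a Foxp3-inducing transcription factor, measured 79.0 ± 8.35 CPM in DEL-1-Fc and 65.8 ± 2.97 CPM in Fc. Its log2 fold change of 0.26 (SE 0.083) lay above 0 in the same direction as Foxp3 but did not pass the test (adjusted p = 0.0728), although all 3 DEL-1-Fc libraries exceeded all 3 Fc libraries. Runx3, a related factor linked to Th1 and cytotoxic programmes, fell 1.85-fold (log2 fold change -0.89, SE 0.0764, adjusted p = 0.000207), from 137.5 ± 8.64 to 74.5 ± 5.59 CPM. Runx2 (log2 fold change -0.60, adjusted p = 0.0512) and Cbfb, the shared partner of Runx proteins (0.15, adjusted p = 0.121), did not pass. Foxp3 (ENSMUSG00000039521) lies on the plus strand of chromosome X from 7573644 to 7595245 in GRCm38, where it overlaps Flicr on the same strand and Ccdc22 and Ppp1r3f on the other, so some of its reads are uncertain. Runx1 (ENSMUSG00000022952) lies on the minus strand of chromosome 16 from 92601466 to 92826149, with the predicted gene Gm26626 on the other strand. The Foxp3 call was lost without Fc replicate 1 (log2 fold change 0.46, adjusted p = 0.0873), without Fc replicate 3 (0.52, adjusted p = 0.0753) and without DEL-1-Fc replicate 1 (0.55, adjusted p = 0.0928), while over all alternative settings the adjusted p ranged from 0.00017 to 0.0928. Runx1 passed without DEL-1-Fc replicate 1 (0.31, adjusted p = 0.0222), as did Runx2 (-0.44, adjusted p = 0.0292) and, without DEL-1-Fc replicate 2, Runx2 again (-0.81, adjusted p = 0.0086), and over all alternative settings the adjusted p ranged from 0.00549 to 0.241 for Runx1 and from 0.00499 to 0.175 for Runx2.

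Among genes of other helper T cell fates, Tbx21, which encodes the Th1 regulator T-bet, fell 2.26-fold (log2 fold change -1.18, SE 0.0642, adjusted p = 4.4e-05), from 162.1 ± 10.4 to 71.7 ± 0.69 CPM (SD, n = 3). Ifng, encoding the Th1 cytokine interferon-γ, fell 2.81-fold (-1.49, SE 0.147, adjusted p = 0.000418), and Gata3, the Th2 regulator, fell 1.47-fold (-0.56, SE 0.0901, adjusted p = 0.00437). Tbx21 spans 97098071 to 97115331 on chromosome 11. Both Gata3 and Ifng overlap another annotated gene, so their reads are less certain.

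**Figure D1:**
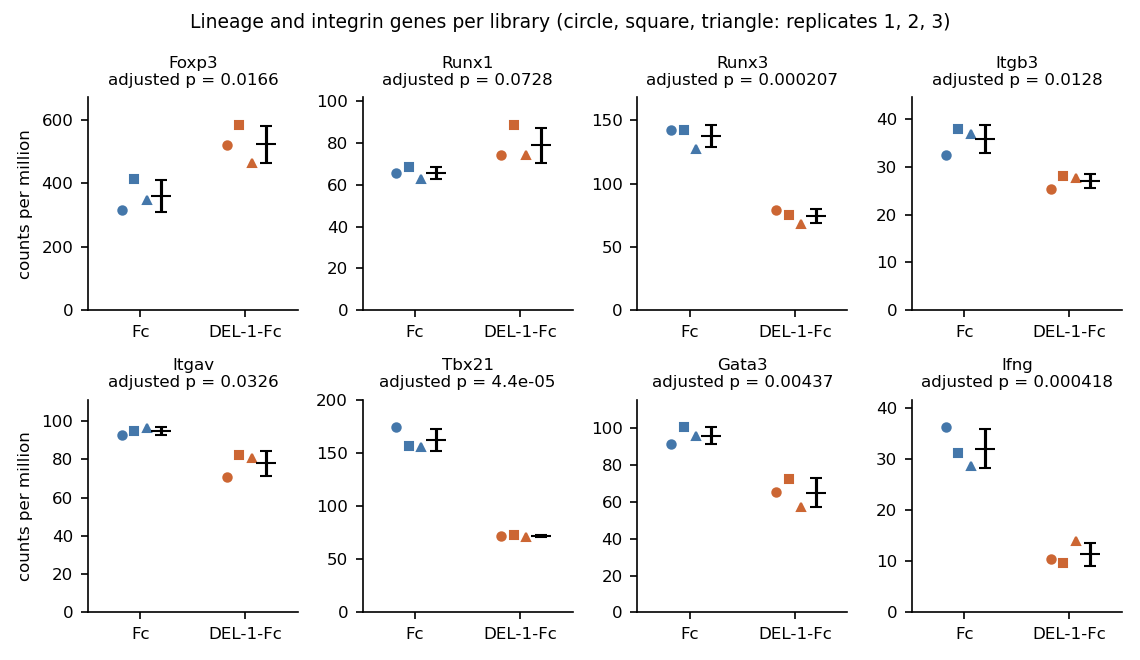
CPM (linear axis from 0) of 8 genes in each of the 3 Fc and 3 DEL-1-Fc libraries, with the group mean and SD as a bar beside the points. Foxp3 lies higher in all 3 DEL-1-Fc libraries, Runx3, Itgb3, Itgav, Tbx21, Gata3 and Ifng lie lower in all 3, and Runx1 lies higher in all 3 without passing the test.

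Among the 17 tested members of the Th1 list, 4 rose and 9 fell (5 and 9 when adjusted over the list alone). The fallers included Eomes, a T-box factor of effector T cells (log2 fold change -0.93, SE 0.0741), Ccl5, a chemokine (-1.53, SE 0.141), and Il12rb2, the IL-12 receptor chain (-1.31, SE 0.165; named after its values were seen). The risers included Il18r1, an IL-18 receptor chain (1.35, SE 0.088). The Th1 list as a whole did not pass limma's camera test (adjusted p = 0.0506). It passed camera without Fc replicate 1 (adjusted p = 0.0493) and without Fc replicate 3 (adjusted p = 0.0495), and also with limma-voom (0.0301), upper-quartile factors (0.0489), library sizes alone (0.0302), no low-count filter (0.0467) and a prior count of 5 (0.0494). Fry, which does not compare a list with other genes, called the Th1 list lower (adjusted p = 0.00205).

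Of 16 tested Th2 members, 2 rose and 6 fell (2 and 8 adjusted over the list alone), and the list was called lower (camera adjusted p = 0.0131; adjusted p = 0.33 with an estimated correlation). Csf2, which encodes the cytokine GM-CSF, fell 3.83-fold (-1.94, SE 0.0733) and Il13, a Th2 cytokine, fell 5.55-fold (-2.47, SE 0.182). Ccr8, a chemokine receptor shared by Th2 cells and Tregs, fell (-0.77, SE 0.0596), whereas the transcription factor Maf rose (1.43, SE 0.105). The list call was lost without Fc replicate 2 (adjusted p = 0.0528).

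Of 16 tested Th17 members, 7 rose and 5 fell (7 and 7 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.271). Fry called it higher (adjusted p = 0.000195). Il17f, a Th17 cytokine, rose 3.54-fold from a low level (1.67 ± 0.184 to 5.93 ± 0.998 CPM, SD, n = 3; log2 fold change 1.82, SE 0.161). Stat3, the transcription factor downstream of IL-6, fell (-0.44, SE 0.0614; it overlaps Stat5a on the other strand), as did Basp1 (-0.70, SE 0.0961). Il17a counts were 5, 4 and 2 in Fc and 5, 6 and 21 in DEL-1-Fc, too few to be tested. Without Fc replicate 1, 2 or 3 the Th17 fallers numbered 2, 3 and 2. Of 12 tested Tfh members, 4 rose and 2 fell (5 and 5 adjusted over the list alone), with camera adjusted p = 0.151. The 4 risers were Slamf6 (1.33, SE 0.0905), Pou2af1 (1.52, SE 0.104), Maf and Bcl6, the Tfh-defining repressor (0.89, SE 0.131), and the fallers numbered 4 without DEL-1-Fc replicate 1 and 0 or 1 without any other library.

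Across the transcriptome, 1884 of 14928 tested genes (12.6%) differed between DEL-1-Fc and Fc at an edgeR adjusted p under 0.05. Of these, 956 were higher and 928 lower in DEL-1-Fc. The fold change was at least 2 in either direction (absolute log2 of 1 or more) for 413 genes, 247 higher and 166 lower. In all 1884 called genes the 3 libraries of one group lay entirely above those of the other. Such separation held for 34.8% of all tested genes, where chance gives 10%. The number of calls rested on the libraries used: it was 901, 970 and 963 without Fc replicates 1, 2 and 3, and 3003 without DEL-1-Fc replicate 1, of which 1832 were shared with the full set. Without DEL-1-Fc replicate 3 it was 1295.

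The largest rises were in H19, an imprinted non-coding RNA, which went from 8.24 ± 1.49 to 44.2 ± 2.46 CPM (SD, n = 3; log2 fold change 2.42, SE 0.128, adjusted p = 4.39e-05), and in Ccl1, a chemokine that binds Ccr8 (2.10, SE 0.137). Drc1, a dynein regulator of cilia (2.09, SE 0.0978), Aqp3, a water and glycerol channel (1.85, SE 0.137), Xcl1, a chemokine for cross-presenting dendritic cells (1.81, SE 0.075), and Pfn2, an actin-binding profilin (1.75, SE 0.118), came next. Ramp1, a receptor partner for the neuropeptide CGRP, Hsd11b1, which regenerates active glucocorticoid, Trib2, a pseudokinase, and Emp1, a membrane protein, rose by log2 values of 1.70, 1.68, 1.64 and 1.62. Xcl1 had the highest level of these, at 258.5 ± 5.5 CPM in DEL-1-Fc against 73.6 ± 6.5 CPM in Fc.

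The largest falls included Il13 and Csf2, Atf3, a stress-induced transcription factor (log2 fold change -2.08, SE 0.125, from 83.3 ± 4.67 to 19.7 ± 3.74 CPM, SD, n = 3), and Ccdc184 (-1.98, SE 0.103). The interferon-stimulated genes Mx1 (-2.01, SE 0.26), Rsad2 (-1.96, SE 0.171) and Oasl1 (-1.86, SE 0.179) were among them. Ifi211 (-2.54, SE 0.145) and Serpina3f (-1.71, SE 0.154) belong to multigene families and shared 54.4% and 27.4% of their 31-base words with other genes, so reads may be split among copies. Nanp, which acts in sialic acid synthesis, had the largest fall (-4.62, SE 0.935, adjusted p = 0.0469). It measured 10.4, 12.1 and 11.3 CPM in Fc and 0.152, 1.08 and 0.0675 CPM in DEL-1-Fc, shared 52.6% of its 31-base words with other genes and overlaps Ninl on the same strand. The Nanp call was lost without Fc replicate 1, 2 or 3 (adjusted p = 0.146, 0.153 and 0.147) and without DEL-1-Fc replicate 1 (adjusted p = 0.0922). The other largest changes stayed called in each of the 6 omissions of a library.

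Treg signature genes split between the groups. Of 39 tested members, 10 rose and 12 fell (11 and 13 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.271). Fry, which does not compare a list with other genes, called it lower (adjusted p = 0.0114). Nt5e, the ectoenzyme CD73, rose 2.08-fold (log2 fold change 1.06, SE 0.0794) and Gpr83, a receptor enriched in Tregs, rose 2.13-fold (1.09, SE 0.0839, from 64.5 ± 5.22 to 137.3 ± 10.9 CPM, SD, n = 3). Tigit, an inhibitory receptor, fell 2.09-fold (-1.06, SE 0.0735), and Ctla4 fell (-0.30, SE 0.0754, adjusted p = 0.031) from 524.1 ± 13.7 to 424.5 ± 35 CPM. Il2ra, the IL-2 receptor α chain (log2 fold change 0.05, SE 0.0924), Ikzf2, encoding Helios (-0.10, SE 0.0961), and Tgfb1 (-0.23, SE 0.148) did not pass. Il10 counts were 5, 10 and 4 in Fc and 0, 9 and 0 in DEL-1-Fc, near the limit of 3 counts and not tested. Without Fc replicate 1, 2 or 3 the risers numbered 6, 6 and 5. The Ctla4 call was lost without Fc replicate 1, 2 or 3 (adjusted p = 0.113, 0.106 and 0.135) or DEL-1-Fc replicate 2 (adjusted p = 0.0613), and with library sizes alone (adjusted p = 0.0616).

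Of 38 tested regulators of the Foxp3 locus, 2 rose and 7 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.195). Nr4a3, an orphan nuclear receptor induced by T cell receptor signals, fell from 1137 ± 38.7 to 681.1 ± 77 CPM (SD, n = 3; log2 fold change -0.74, SE 0.0904). Gfi1, a repressor (-0.52, SE 0.0688), and Satb1, a chromatin organiser (-0.43, SE 0.0649), also fell. The 2 that rose were Smad3, which transmits TGF-β signals (0.41, SE 0.0719), and Foxp1 (0.27, SE 0.0653), both named after their values were seen. The list passed without DEL-1-Fc replicate 2 (adjusted p = 0.0335), when 11 fell and 1 rose, and it had 4 risers without DEL-1-Fc replicate 1 and 1 without any one Fc replicate. The Foxp1 call was lost without Fc replicate 1, 2 or 3 (adjusted p = 0.114, 0.0953 and 0.139) or DEL-1-Fc replicate 2 (0.0602).

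Of 26 tested TGF-β response genes, 6 rose and 6 fell (8 and 6 adjusted over the list alone), with a median log2 fold change of 0.03, a mean of -0.03 and a camera adjusted p of 0.682. Among them Bhlhe40, a repressor of Il10 (-0.96, SE 0.0648), Cdkn1a, the cell cycle inhibitor p21 (-1.09, SE 0.0814), and Furin, a protease that matures TGF-β (-0.65, SE 0.0724), fell. Of 24 tested IL-2 and STAT5 targets, 4 rose and 7 fell (4 and 8 adjusted over the list alone), called lower with camera adjusted p = 0.0442 (adjusted p = 0.528 with an estimated correlation). Gzmb, encoding granzyme B, fell from 992.9 ± 18.1 to 450.1 ± 52.8 CPM (SD, n = 3; -1.14, SE 0.0898), Gadd45b (-0.62, SE 0.0756) and Dusp5 (-0.53, SE 0.0666) also fell, and Prf1, encoding perforin, rose (1.05, SE 0.146). This list call was lost without Fc replicate 2 (adjusted p = 0.112), DEL-1-Fc replicate 2 (0.0862) or DEL-1-Fc replicate 3 (0.127), and without pseudogenes and shared-sequence genes (0.226). Without Fc replicate 1, 2 or 3 the TGF-β list had 3, 1 and 3 risers, and without Fc replicate 1 or 3 the IL-2 list had 2.

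Integrin genes were called in both directions. Itgb3, the β3 chain, fell 1.32-fold (log2 fold change -0.40, SE 0.0816, adjusted p = 0.0128), from 35.8 ± 2.95 to 27.0 ± 1.51 CPM (SD, n = 3), and Itgav, the αv chain, fell 1.22-fold (-0.28, SE 0.0713, adjusted p = 0.0326). Itgb8, a chain that helps activate TGF-β, fell 2.48-fold (-1.31, SE 0.192). Itgb7, the β7 chain of gut homing (0.93, SE 0.104), and Itga6 (0.69, SE 0.0745) rose, as did Itgae, the αE chain that pairs with β7, from a low level (0.76, SE 0.173; named after its values were seen). Of the 22 tested members of the list, 3 rose and 5 fell (3 and 6 adjusted over the list alone). The list had a median log2 fold change of -0.04, a mean of 0.01 and was not called (camera adjusted p = 0.648). Endogenous Edil3 had 0, 0 and 1 counts in Fc and 0 in each DEL-1-Fc library, and a count of 0 allows up to 0.0899 CPM in the shallowest library. The fallers of the list numbered 2, 2 and 1 without Fc replicates 1, 2 and 3, and 3 without DEL-1-Fc replicate 3. The call of Itgb3 was lost without Fc replicate 2 (adjusted p = 0.0697) or Fc replicate 3 (0.0718), that of Itgae without Fc replicates 2 or 3 (0.0962 and 0.0952) or DEL-1-Fc replicates 2 or 3 (0.0591 and 0.0542), and that of Itgav without any one Fc replicate (0.11, 0.125 and 0.135) or DEL-1-Fc replicate 3 (0.0651). Itgav also lost its call with library sizes alone (0.0755) and after thinning (0.0524), and Itgae with the replicate block (0.0557) and after thinning (0.0767).

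Of 38 tested T cell receptor activation genes, 4 rose, 15 fell and 19 did not pass (6 and 20 adjusted over the list alone), and the list was called lower (camera adjusted p = 0.000685; adjusted p = 0.436 with an estimated correlation). Cd44, an adhesion receptor of activated cells, fell from 367.3 ± 10.6 to 210.7 ± 7.59 CPM (SD, n = 3; log2 fold change -0.80, SE 0.0612), and Zbtb32, a repressor induced on activation, fell (-0.75, SE 0.0877). Egr2, an immediate early factor, rose (0.57, SE 0.0685). NF-κB targets had 0 risers and 7 fallers of 18 tested (1 and 8 adjusted over the list alone; camera adjusted p = 0.0283, adjusted p = 0.375 with an estimated correlation). Icam1, an adhesion ligand (-0.54, SE 0.054), Nfkb2, an NF-κB subunit (-0.40, SE 0.0625), Tnfaip3, a feedback inhibitor (-0.33, SE 0.0608), and Cd83 (-0.34, SE 0.0678) fell. The NF-κB list call was lost without Fc replicate 2 (adjusted p = 0.0528) or DEL-1-Fc replicate 3 (0.11), the Tnfaip3 call without Fc replicate 2 (0.0521) and the Cd83 call without Fc replicates 1 or 3 (0.0638 and 0.0647). Without Fc replicates 1, 2 and 3 and DEL-1-Fc replicate 3, the T cell receptor fallers numbered 7, 7, 8 and 9, and the NF-κB fallers 3, 3, 3 and 4.

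Of 28 tested cytokine genes, among them Csf2 and Il13, 4 rose and 9 fell (4 and 11 adjusted over the list alone; called lower, camera adjusted p = 0.0184, adjusted p = 0.33 with an estimated correlation), and that call was lost without Fc replicate 2 (adjusted p = 0.0505). Of 21 chemokine and receptor genes, 6 rose and 5 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.358), with Xcl1 and Ccl1 up and Ccr8 and Ccl5 down. Of 13 cytotoxic effector genes, 4 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.271). Besides Gzmb, the fallers held Serpinb6b, a protease inhibitor (log2 fold change -0.60, SE 0.0604), and Klrk1, the NKG2D receptor, at a low level (-1.84, SE 0.255), and the protease gene Ctsw rose (0.93, SE 0.0827). Of 15 inhibitory receptor genes, 5 rose and 5 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.963), with Cd160 (0.82, SE 0.0871) and Vsir, encoding VISTA (0.67, SE 0.075), among the risers. Of 23 naive and quiescence genes, 7 rose and 4 fell (12 and 7 adjusted over the list alone; camera adjusted p = 0.195). Rasgrp2, a Rap1 activator (1.44, SE 0.133), rose, while Klf6 (-0.60, SE 0.0581) and Dapl1 (-0.71, SE 0.0741) fell. Without any one Fc replicate the cytotoxic risers numbered 2 and the inhibitory receptor fallers 2, and the latter also numbered 2 without DEL-1-Fc replicate 2.

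Of 30 tested interferon-stimulated genes, 16 fell, 2 rose and 12 did not pass (19 and 3 adjusted over the list alone), and the list was called lower (median log2 fold change -0.55, camera adjusted p = 2.98e-06; adjusted p = 0.464 with an estimated correlation). Oas3, an antiviral RNA sensor, fell from 184.2 ± 16.1 to 73.7 ± 6.87 CPM (SD, n = 3; -1.32, SE 0.0896), Ifi44 fell 2.85-fold (-1.51, SE 0.115), and Usp18, which restrains interferon signalling, fell 3.14-fold (-1.65, SE 0.125). The 2 that rose were the guanylate-binding proteins Gbp2 (0.72, SE 0.0744, from 494.6 ± 36.5 to 812.3 ± 20 CPM) and Gbp3 (0.59, SE 0.0793). Of 20 genes of antigen presentation, 2 rose and 5 fell (2 and 9 adjusted over the list alone; called lower, camera adjusted p = 0.0283, adjusted p = 0.509 with an estimated correlation). H2-Q6 (-0.91, SE 0.088) and H2-Q7 (-0.39, SE 0.0702) share 51.8% and 37.4% of their 31-base words with other genes and are uncertain. Tapbp, a peptide-loading factor, fell (-0.36, SE 0.0693), and H2-Aa rose from a low level (0.82, SE 0.164). Beside these 2 lists, dendritic cell markers summed to 357.0 ± 10.8 CPM in Fc and 234.5 ± 28.4 CPM in DEL-1-Fc (SD, n = 3), with 3 of 5 tested genes lower, and macrophage and monocyte markers to 245.6 ± 13.2 and 194.4 ± 11.9 CPM, with 2 of 7 lower. Most of the macrophage and monocyte sum came from 1 gene, Ctss (mean 146.8 CPM). The dendritic cell sum is not separate from the 2 lists. Its highest gene, Bst2 (mean 142.9 CPM), is also in the interferon list, and Cd74 and H2-Ab1 are in the antigen presentation list. The antigen presentation call was lost without Fc replicate 2 (adjusted p = 0.0608), Fc replicate 3 (0.0728), DEL-1-Fc replicate 2 (0.157) or DEL-1-Fc replicate 3 (0.0635), and without pseudogenes and shared-sequence genes (0.454), with 2 fallers without Fc replicate 2 or 3 and 11 without DEL-1-Fc replicate 1. The Tapbp call was lost without Fc replicates 2 or 3 (adjusted p = 0.0648 and 0.0668) and the H2-Aa call without Fc replicates 1 or 2 (0.0531 and 0.0649).

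Of 24 tested ATF4 and amino acid response genes, 0 rose, 14 fell and 10 did not pass (0 and 17 adjusted over the list alone), and the list was called lower (median log2 fold change -0.38, camera adjusted p = 6.96e-09; adjusted p = 0.33 with an estimated correlation). Chac1, which degrades glutathione, fell 4.66-fold (log2 fold change -2.22, SE 0.126), Atf3 fell 4.22-fold, Sesn2, a leucine sensor, fell 2.44-fold (-1.29, SE 0.0793), and Asns, asparagine synthetase, fell 2.23-fold (-1.16, SE 0.0922, from 44.5 ± 1.28 to 19.98 ± 2.5 CPM, SD, n = 3). Atf4 itself fell from 506.8 ± 10.1 to 363.1 ± 4.89 CPM (-0.48, SE 0.0591; named after its values were seen). Of 19 p53 target and apoptosis genes, 2 rose and 9 fell (3 and 10 adjusted over the list alone; called lower, camera adjusted p = 0.00932, adjusted p = 0.33 with an estimated correlation). Besides Sesn2 and Cdkn1a, Perp, a membrane effector of apoptosis, fell (-0.63, SE 0.0733), and Sesn1 rose (0.65, SE 0.0659). The ATF4 fallers numbered 9 without Fc replicate 1 and the p53 fallers 5 without Fc replicate 3, with both lists still called.

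**Figure D2:**
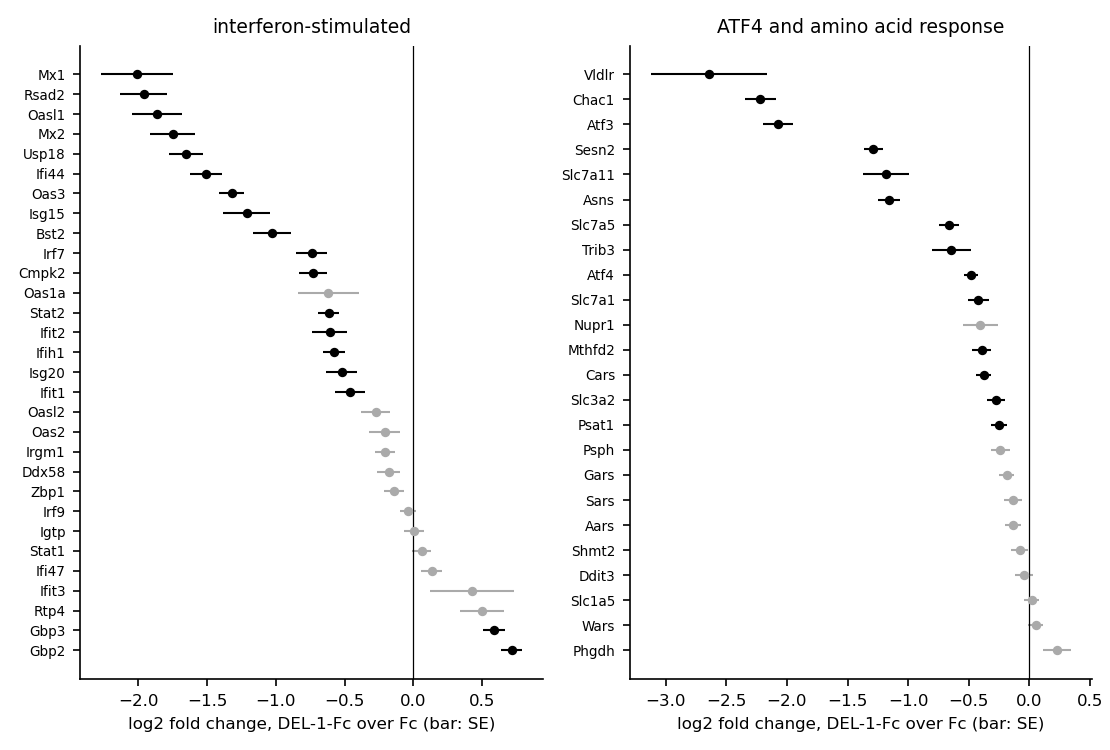
Log2 fold change of DEL-1-Fc over Fc (x axis, log scale, 3 libraries per group) with its SE as a bar for the 30 interferon-stimulated and 24 ATF4 and amino acid response genes tested. Black points passed the edgeR test and grey points did not, with 16 and 14 genes called lower and only Gbp2 and Gbp3 called higher.

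Smaller calls came from the other stress lists. Of 20 endoplasmic reticulum stress and folding genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.0389, adjusted p = 0.364 with an estimated correlation): Edem1, a factor of misfolded protein disposal (log2 fold change -0.43, SE 0.0643), Atf6 (-0.36, SE 0.0836) and Syvn1 (-0.32, SE 0.078). Of 13 heat shock genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.0493, adjusted p = 0.464 with an estimated correlation): Hspa1b (-1.33, SE 0.189), Hspa1a (-1.30, SE 0.34) and Hsp90aa1 (-0.31, SE 0.0717), which share 68.1%, 70.1% and 62.9% of their 31-base words with other genes. The endoplasmic reticulum list call was lost without Fc replicates 2 or 3 (adjusted p = 0.0528 and 0.0733), DEL-1-Fc replicates 2 or 3 (0.104 and 0.0555) or the shared-sequence genes (0.0703), and the heat shock list call without Fc replicates 1, 2 or 3 (0.05, 0.0528 and 0.0733), DEL-1-Fc replicates 2 or 3 (0.247 and 0.0598) or the shared-sequence genes (0.52). The calls of Atf6, Syvn1, Hsp90aa1 and Hspa1a were lost without any one Fc replicate or DEL-1-Fc replicate 3 (highest adjusted p = 0.112, 0.134, 0.119 and 0.155) and that of Hspa1a also without DEL-1-Fc replicate 2 (0.0984), leaving 1 faller per list without an Fc replicate, against 7 and 4 without DEL-1-Fc replicate 1.

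Of 20 glycolysis genes, 0 rose, 5 fell and 15 did not pass (0 and 5 adjusted over the list alone; camera adjusted p = 0.00239, adjusted p = 0.375 with an estimated correlation). Hk2, hexokinase 2, fell from 180.6 ± 1.91 to 115.4 ± 3.08 CPM (SD, n = 3; log2 fold change -0.65, SE 0.0546), and Slc16a3, a lactate exporter (-0.72, SE 0.0924), Pfkp (-0.41, SE 0.0646) and Slc2a1, the glucose transporter GLUT1 (-0.26, SE 0.0652), fell too. Of 20 hypoxia genes, 1 rose, 8 fell and 11 did not pass (1 and 9 adjusted over the list alone; camera adjusted p = 0.0184, adjusted p = 0.464 with an estimated correlation), among them the oxygen sensor Egln3 (-0.76, SE 0.065), Adm (-0.77, SE 0.0845), Ero1l (-0.48, SE 0.0704) and Vegfa (-0.75, SE 0.12). The riser was Ndrg1 (0.40, SE 0.0922; named after its values were seen). Of 13 fatty acid synthesis genes, 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.0184, adjusted p = 0.375 with an estimated correlation). The desaturase genes Fads2 (-1.26, SE 0.0628), Scd1 (-1.20, SE 0.0878) and Scd2 (-0.75, SE 0.0894, from 1421 ± 11.1 to 845.1 ± 94 CPM) fell, and the elongase gene Elovl6 rose (0.33, SE 0.066). The hypoxia list call was lost without Fc replicate 2 (adjusted p = 0.058), that of Slc2a1 without Fc replicates 2 or 3 (0.169 and 0.139) or DEL-1-Fc replicates 2 or 3 (0.0677 and 0.0779), that of Elovl6 without Fc replicates 1, 2 or 3 (0.0783, 0.0626 and 0.0586) and that of Ndrg1 without Fc replicates 1 or 2 (0.0852 and 0.061). Glycolysis fallers numbered 10 without DEL-1-Fc replicate 1 and 3 without Fc replicate 2 or 3 or DEL-1-Fc replicate 2 or 3, hypoxia fallers 5 without Fc replicate 2 or 3, and fatty acid fallers 5 without DEL-1-Fc replicate 1.

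The 2 lists called higher rested on DEL-1-Fc replicate 1. Of 32 nuclear oxidative phosphorylation genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.653 with an estimated correlation), and without DEL-1-Fc replicate 1 the adjusted p was 0.528. The riser was Cox5b, a cytochrome oxidase subunit (log2 fold change 0.27, SE 0.0754), while Atp5j (0.15), Ndufa4 (0.24) and Cox6c (0.22) did not pass. Of 32 cytosolic ribosomal protein genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.0414, adjusted p = 0.653 with an estimated correlation), and without DEL-1-Fc replicate 1 the adjusted p was 0.8. The riser was Rpl14 (0.58, SE 0.13), while Rplp0 (0.39) and Rpl5 (0.83) did not pass, and these 3 genes share 42.7%, 53.3% and 94.8% of their 31-base words with other genes. Without pseudogenes and shared-sequence genes the ribosomal list had an adjusted p of 0.437. In DEL-1-Fc replicate 1, genes with symbols starting with Rpl or Rps and a digit took 5.89% of all counts, against 4.58% to 5.23% in the other 5 libraries. That share takes in ribosomal pseudogenes and leaves out Rplp0. Without Fc replicate 2 the adjusted p of these lists was 0.0942 and 0.0679, and without Fc replicate 1 that of the ribosomal list was 0.096. The Cox5b and Rpl14 calls were lost without any one Fc replicate (highest adjusted p = 0.189 and 0.0929) or DEL-1-Fc replicate 3 (0.129 and 0.0639), while Rplp0 passed without Fc replicate 2 (0.018) and Ndufa4 without DEL-1-Fc replicate 2 (0.0412). Cox5b also lost its call with limma-voom (adjusted p = 0.0609), RLE factors (0.052), no robust dispersion (0.0551), the replicate block (0.0722) and thinning (0.0501).

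Few cell cycle genes were called. Of 26 G1/S and replication genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.0724), and of 26 mitosis genes 2 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.295). The G1/S list passed without DEL-1-Fc replicate 2 (adjusted p = 0.0335), with limma-voom (0.043) and with library sizes alone (0.0333). Sterol biosynthesis had 0 risers and 2 fallers of 24 (0 and 2 adjusted over the list alone; camera adjusted p = 0.0748, 0.0168 without DEL-1-Fc replicate 1 and 0.043 with limma-voom), and ribosome biogenesis 1 riser and 0 fallers of 24 (0 and 0 adjusted over the list alone; camera adjusted p = 0.295). In all, 16 of 31 lists were called, 2 higher and 14 lower, and 6 of the 16 stayed called in each of the 6 omissions of a library: T cell receptor activation, glycolysis, fatty acid synthesis, ATF4, interferon-stimulated and p53. Some lists share genes and are not independent. Csf2 and Il13 are in the Th2 and cytokine lists, Sesn2 in the ATF4 and p53 lists and Slc2a1 in the glycolysis and hypoxia lists. With an estimated correlation between genes camera called 0 lists (lowest adjusted p = 0.33). For Th2, cytokines, p53 and endoplasmic reticulum stress the estimated correlations were 0.00744, -0.000932, -0.0274 and -0.00673, below the preset 0.01. A higher correlation therefore does not account for the loss of these calls, and its cause was not tested. Limma's fry asks whether a list's genes move on balance in a direction, without comparing them with other genes, and called 19. Camera with the preset correlation and fry differed in the lists called. Fry alone called Treg signature (adjusted p = 0.0114), Th1 (0.00205), TGF-β response (0.0446) and cytotoxic effector (0.0337) lower. It alone called Th17 (0.000195), Tfh (0.00109) and chemokines (0.0317) higher. Fry did not call IL-2 and STAT5 targets (0.0766), oxidative phosphorylation (0.328), ribosomal proteins (0.372) or antigen presentation (0.0858).

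**Figure D3:**
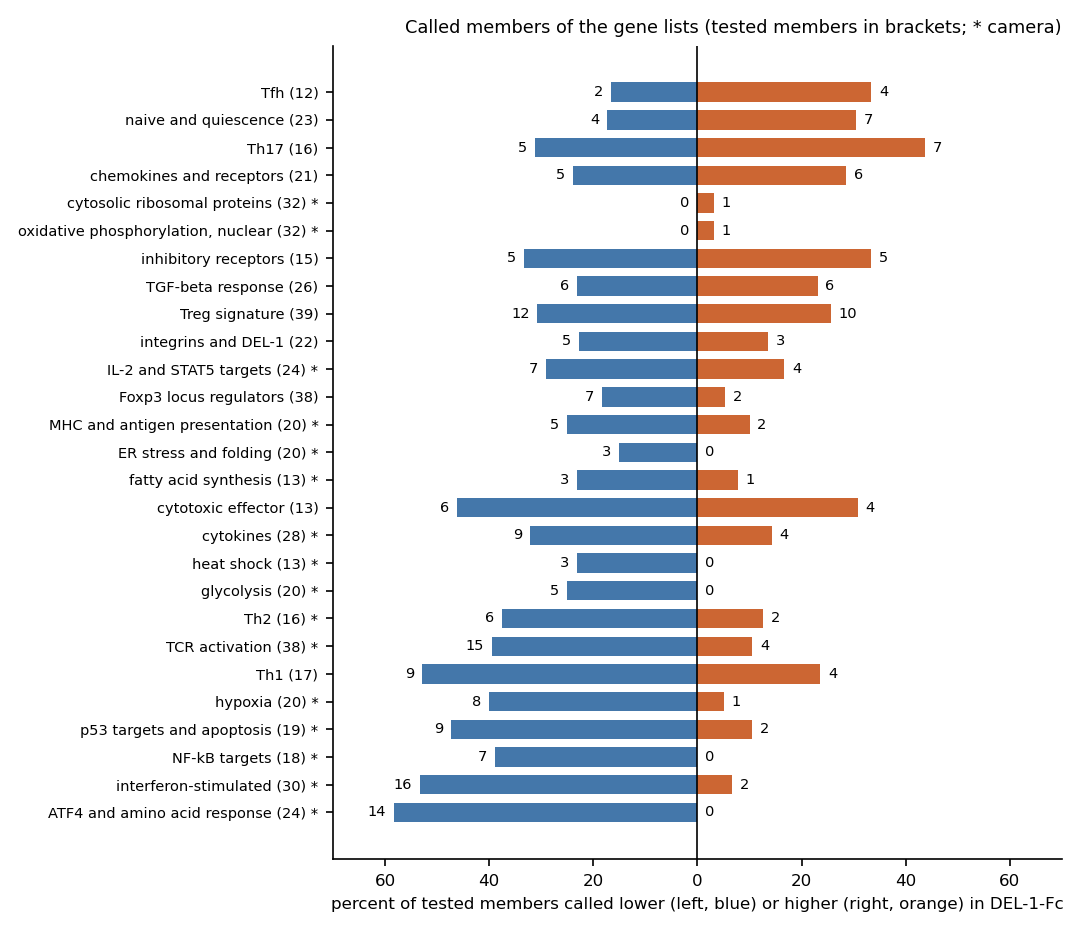
Percent of the tested members of each gene list described by named genes that were called lower (left) or higher (right) in DEL-1-Fc (3 libraries per group), with the number of called members beside each bar and tested members in brackets. Stars mark the 16 lists called by camera with the preset correlation, and the ATF4 list has 14 fallers and 0 risers of 24.

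Markers of other spleen cells varied in level, and some of them are also made by T cells. Pan T cell markers summed to 6830 ± 121 CPM in Fc and 6874 ± 496 CPM in DEL-1-Fc (SD, n = 3). Of 12 tested B cell markers 2 rose and 1 fell, and their sum was 384.8 ± 11.8 and 478.9 ± 19.3 CPM, mostly from Ighm, the IgM heavy chain (log2 fold change 0.32, SE 0.0636). Plasma cell markers summed to 8.93 ± 1.5 and 6.68 ± 0.407 CPM, with 0 of 6 up and Igkc down (-0.71, SE 0.145). Macrophage and monocyte markers had 0 risers and 2 fallers of 7, summing to 245.6 ± 13.2 and 194.4 ± 11.9 CPM, and Mpeg1 fell (-1.52, SE 0.149). Most of that sum came from Ctss (mean 146.8 CPM), while the median marker of the list lay at 0.0732 CPM. Dendritic cell markers had 0 risers and 3 fallers of 5, summing to 357.0 ± 10.8 and 234.5 ± 28.4 CPM, and Bst2, which is also interferon-stimulated, fell (-1.03, SE 0.139). CD8 T cell markers had 2 risers and 1 faller of 4 (237.9 ± 13.2 and 164.2 ± 4.56 CPM), with Cd8a at a low level (0.78, SE 0.135) and most of the sum from Eomes, which is also in the Th1 list, and γδ and innate-like T cell markers 2 risers and 0 fallers of 4 (2.16 ± 0.152 and 4.42 ± 0.756 CPM). NK cell markers summed to 5.22 ± 0.413 and 3.89 ± 0.419 CPM with 1 riser and 1 faller of 4. Stromal and endothelial markers (63.2 ± 5.46 and 80.7 ± 6.09 CPM) and neutrophil markers (0.97 ± 0.366 and 1.85 ± 0.332 CPM) had 1 riser each of 3 and 1 tested. Nearly all of the stromal and endothelial sum came from Pecam1 (mean 71.1 CPM). Mast cell (2.19 ± 0.248 and 2.97 ± 0.28 CPM), erythroid (1.504 ± 0.154 and 1.61 ± 0.0375 CPM) and megakaryocyte markers (1.48 ± 0.16 and 1.11 ± 0.207 CPM) had 0 called members. The Ighm call was lost without Fc replicates 1 or 3 (adjusted p = 0.0824 and 0.0789) and the Igkc call without Fc replicate 1 (0.0754).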

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

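The length and GC trend removal, the thinning and the omission of pseudogenes and shared-sequence genes were chosen after seeing the data, and the other settings before. All 1884 called genes kept their direction in every setting that gave them a value, which for the omissions follows from their separated libraries. The count of calls changed with the libraries used. Leaving out a library gave 901 to 3003 calls, with 428 to 1485 higher and 466 to 1518 lower, the lowest without Fc replicate 1 (for lower calls without Fc replicate 2) and the highest without DEL-1-Fc replicate 1. Each omission has fewer samples, which lowers the power, and the cause of the high count was not tested. An absolute log2 fold of at least 1 left 413 calls, 247 higher and 166 lower. Other settings stayed within 1.5 times of 1884, from 1394 with the 5 CPM filter to 2742 with the length and GC trend removed, and library sizes alone moved the share of higher calls from 50.7% to 59.8%. Foxp3 ranged from 0.46 to 0.66 over the omissions and lost its call in 3 of them. Runx1 ranged from 0.17 to 0.31 over the omissions and passed with DESeq2 (0.26, adjusted p = 0.0461), with the length and GC trend removed (0.32, adjusted p = 0.00549) and without pseudogenes and shared-sequence genes (0.27, adjusted p = 0.0395); the cause was not tested. Called gene lists numbered 6 to 16 over the omissions, 6 without Fc replicate 2, and 0 with an estimated correlation. The 5 CPM filter left 12 lists called, without IL-2 and STAT5 targets (0.11), cytokines (0.0716), endoplasmic reticulum stress (0.0572) and heat shock (0.11), and the omission of shared-sequence genes 11. Library sizes alone ended the endoplasmic reticulum call (0.0504), and thinning those of IL-2 and STAT5 targets (0.0536) and heat shock (0.0558). Removing the trend ended that of ribosomal proteins (0.101). Il2ra, not called, ranged from -0.01132 to 0.1285 over the omissions, negative without DEL-1-Fc replicate 2. Of the other single-gene values, 2555 kept direction and side of the threshold, 97 lost and 20 gained the call. With group means subtracted, correlations between same-number libraries of the 2 groups were 0.0163, 0.0885 and 0.0425. Between different-number libraries of the 2 groups they ran from -0.0913 to 0.0382. The same-number values were small but all positive, so they do not settle whether libraries were paired by replicate number. With the replicate number as a block, 1510 genes (733 higher, 777 lower) and 13 lists were called, without IL-2 and STAT5 targets (adjusted p = 0.0512), NF-κB targets (0.0538) and antigen presentation (0.0512), with Foxp3 and Runx1 on the same side of the threshold. Camera was not run for DESeq2, which gives no log CPM, or without robust dispersion, which leaves log CPM as it is. Depth limits genes near 0.0899 CPM in DEL-1-Fc replicate 1.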

Other observations

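The tests in this part that use thinning, trend removal or the omission of shared-sequence genes were chosen after the data were seen, the last after the outlying genes had been seen, though each bound was written before the value that decides it. The genes of this and the next paragraph were not named by the rule and were chosen after their values were seen, so they are no further evidence for any list. Ly6a, the surface protein Sca-1, which interferons induce, fell from 379.6 ± 14.1 to 135.3 ± 30.2 CPM (SD, n = 3; log2 fold change -1.49, SE 0.141, adjusted p = 0.000452). Trim30a (-1.13, SE 0.113), Helz2 (-0.85, SE 0.0963), Rnf213 (-0.86, SE 0.139) and Eif2ak2, the RNA-activated kinase PKR (-0.90, SE 0.1), also fell. A guanylate-binding protein outside the list, Gbp7, rose as Gbp2 and Gbp3 did (0.65, SE 0.102). Gpt2, an alanine aminotransferase, also fell (-1.62, SE 0.111). These genes kept their calls in each of the 6 omissions of a library.

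Plaur, the urokinase receptor that binds vitronectin and integrins, fell from 195.3 ± 4.59 to 71.8 ± 7.41 CPM (SD, n = 3; log2 fold change -1.44, SE 0.0808, adjusted p = 4.4e-05), with Serpine2, an inhibitor of urokinase (-1.47, SE 0.116). Cd80, a ligand of CD28 and CTLA-4, fell 2.37-fold (-1.25, SE 0.0762). Genes that rose included Klf2, a transcription factor that controls S1pr1 (1.56, SE 0.209), S1pr1, the receptor for leaving lymphoid tissue (1.21, SE 0.221), and Igfbp4 (1.39, SE 0.189), which are members of the naive and quiescence list, where 7 rose, 4 fell and the list was not called (camera adjusted p = 0.195). Sgk1, a salt- and glucocorticoid-induced kinase, rose 2.44-fold (1.29, SE 0.0879). The S1pr1 call was lost without Fc replicate 1, 2 or 3 (adjusted p = 0.0667, 0.0652 and 0.0564), and the others held in each omission.

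The number of called genes was set against other splits of the 6 libraries into 3 and 3. Of 10 splits 1, the real one, gave as many as 1884 genes, and the highest other split gave 2. With 10 splits the share cannot fall under 0.1, which is too few for a share under 0.05.

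DEL-1-Fc replicate 1 lay apart from DEL-1-Fc replicates 2 and 3, at 1.42 times their own distance in log CPM. Of the genes over 2-fold outside the range of the other 5 libraries (after adding 0.5 CPM), it had 108, of which 91 were pseudogenes and 102 were pseudogenes or shared sequence, against 11 to 17 such outlying genes in each other library. Rps6-ps3 measured 55.2 CPM there and at most 0.264 elsewhere, and Kpna2, which shares 94.2% of its 31-base words, 190.4 CPM against at least 542.8. The ratio was 1.36 after thinning to the smallest library's total, 1.40 with the length and GC trend removed (a trend with R² of 11.8% in that library and at most 5.29% in the others) and 1.46 without pseudogenes and shared-sequence genes, and the highest median deviation among the 4 cell type marker lists with at least 5 tested genes was 0.334 on the log2 scale (dendritic cells; the others were B cells, plasma cells and macrophages), so none of the total count, the trend, shared sequence or RNA of these 4 cell types alone accounts for the distance. A difference in read layout or in how reads with several matches were assigned could still underlie the pseudogene values, and a difference in the state of the cells stays open, as neither was tested.

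In the interferon-stimulated and ATF4 lists 30 members were called lower, at a median log2 fold change of -0.88 over these 30, while Gbp2 and Gbp3 rose and the other members did not pass. With the length and GC trend removed the 30 were still called lower, and the medians over all tested members, called or not, were -0.54 for the 30 interferon-stimulated and -0.36 for the 24 ATF4 genes, against -0.55 and -0.38 before. Without DEL-1-Fc replicate 1 the median over the 30 called members was -0.99 and 27 of them were called, with medians over all tested members of -0.52 and -0.37. The 30 were picked by their calls in these same libraries. In every called gene the DEL-1-Fc and Fc libraries lay fully apart, so the direction of the 30 without that library was set beforehand. The medians over all tested members did not depend on that choice and changed little. The shift of these lists therefore did not rest on the trend or that library alone. A response of the cells to DEL-1-Fc is a candidate explanation, as is any difference between the cultures that goes with the groups, such as cell density or medium use, which these data cannot address.

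Foxp3 rose while Tbx21 fell. With the length and GC trend removed the Foxp3 log2 fold change was 0.53 (SE 0.106, adjusted p = 0.0104) and that of Tbx21 was -1.21. Without DEL-1-Fc replicate 1 the values were 0.55 (SE 0.161, adjusted p = 0.0928) and -1.17. There the Foxp3 fold was as in the full set (0.54, SE 0.116), but its SE was larger and the call was lost. Foxp3 stayed called without Fc replicate 2, DEL-1-Fc replicate 2 or DEL-1-Fc replicate 3 (edgeR adjusted p = 0.0152, 0.0413 and 0.0214). Its call was also lost without Fc replicate 1 or Fc replicate 3 (edgeR adjusted p = 0.0873 and 0.0753). Whether fewer libraries account for the lost call can therefore not be told. Neither test could have undone the folds. Foxp3 measured 521 CPM in DEL-1-Fc replicate 1, between 584.1 and 464.8 CPM in replicates 2 and 3. Tbx21 measured 71.55 CPM there and 72.46 and 71.11 CPM in replicates 2 and 3. In that library the shortest genes lay 0.187 and the longest -0.192 log2 from Fc, less than either fold. The values per library show that neither fold came from that library alone, and the tests add nothing to this. An effect of DEL-1-Fc on the balance of the 2 factors may account for both folds, as a hypothesis drawn from these same libraries. Whether each cell or the mix of cells changed was not tested.

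Histone genes with symbols starting with Hist took 0.0216% of the counts in DEL-1-Fc replicate 1 and at most 0.00813% in each other library. Hist1h2ao alone measured 109.5 CPM there and at most 5.73 CPM elsewhere. It shares 93.8% of its 31-base words with other genes, so its reads are uncertain. Whether histone genes rose as a group was not tested.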
